A study of Trichoderma atroviride with 42 samples.

How the data were processed

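RNA was sequenced from mycelium of the filamentous fungus Trichoderma atroviride grown on cellophane-covered potato dextrose agar for 36 h in the dark at 27 °C. Mycelium was injured with a scalpel, grazed for 10 min by Drosophila melanogaster larvae, or grazed for 10 min by the collembola Orthonychiurus folsomi, a soil arthropod. It was collected at 4 times from 30 min to 8 h later (30 and 90 min, 4 and 8 h), and untreated plates, opened for 2 min, served as an early and a late control. In the group names used here MI is mechanical injury, Dm the larvae and Of the collembola, and CT0 and CT8 are the early and late controls. The early control carries a time 0 label, while the series' design text places it at 30 min. There were 14 groups of 3 libraries, 42 in all. Per the series' design text the 3 libraries of a group are independent biological replicates, each pooled from 3 technical ones.

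Per the labels' protocols the RNA was total RNA extracted with TRIzol, and the libraries came from a strand-specific total RNA kit. The submitters' processing notes name FastQC 0.11.6, HISAT2 2.1.0 and HTSeq 0.14.1, a read quality tool, an aligner and a read counter. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so overlapping and near-identical genes are uncertain. The authors deposited raw, unnormalized read counts for 12018 transcript models of 11786 genes. In all 204 genes with several models the models held identical counts, so 1 model per gene was used. The authors also deposited 9 tables of log2 fold changes for all but the 3 later O. folsomi groups, and product texts for 2865 of the 3323 genes of the 30 min injury table. Per the file headers these tables also give p-values and false discovery rates. The listed false discovery rates reach 0.005 at most, and the control is not named. For 8 of the 9 tables the authors' log2 fold changes lay nearest to those computed here against the mean of both controls. For the 30 min injury table the mean absolute difference was 0.039 against both controls and 0.163 against CT0. The deposited tables were otherwise used only for the product texts.

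Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered by expression with edgeR's default filter, which left 9193 of 11786, and libraries were scaled with TMM factors. A quasi-likelihood model with 1 coefficient per group was fitted to all 42 libraries, so that all groups shared the estimate of the spread. Treatments at 30 and 90 min were compared with CT0, and treatments at 4 and 8 h with CT8. Larvae were compared with injury and with O. folsomi at each time, and CT8 with CT0, which gave 21 comparisons. P-values were adjusted over all genes tested by the Benjamini-Hochberg method within a comparison. A gene was called changed at an adjusted p under 0.05 with no fold minimum, and the number changed at least 2-fold is given beside. Log2 fold changes carry the standard error that the F statistic of the test implies, the absolute change divided by the square root of F. Levels are CPM (counts scaled by the library total times its TMM factor) with the SD over the 3 libraries of a group. Where adjusted p is printed for a gene it is from this test.

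Gene lists were defined before the data were examined, as word patterns on the product text. Because product texts exist only for 2865 genes that the authors called at 30 min after injury, every list holds only genes selected on these same samples. Counts of list members in that comparison are therefore not independent evidence. The same holds for larvae against injury at 30 min, which shares its injury libraries. For the same reason genes that changed only after grazing are mostly without a text. Of 33 lists, the 25 with at least 5 measured genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, against the other genes with a product text. P-values were adjusted over the lists within a comparison. Camera was repeated with the correlation estimated from the data, where none of the 58 list calls held. Some lists take neighbours of their theme through shared words. The fatty acid list includes isopropylmalate synthase, and the amino acid list an L-PSP endoribonuclease with a chorismate mutase text.

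The genes named were fixed by rule before the data were examined. In each comparison of a treatment with its control or of larvae with injury they are the 4 largest rises and the 4 largest falls among called genes with a product text. Such a gene also had at least 10 CPM in the higher group and no overlap between the libraries of the groups compared. Up to 3 members of each called list were added by the size of change at the same CPM minimum, as were MAP kinases, NADPH oxidases, Dicer and Argonaute proteins where a product text identified them. Of the 308 resulting pairs of gene and comparison the text gives a part, and says where a gene was chosen after its values were seen. Of these, 275 were past the threshold, and 218 of the 275 kept call and direction without each single library of the groups compared.

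Library totals ranged from 1152096 to 5398093 counts. The pipeline was tested on simulated counts for 3 comparisons with 9193 genes each. Every group was drawn from the CT0 means with the fitted spread, and genes were changed in a single group. There 50 genes each were raised 2-fold or 4-fold, or lowered to 0.5-fold or 0.25-fold, all with at least 10 CPM in CT0. Real comparisons changed up to 46.3% of genes and included lower levels, so the rates below hold for the simulated setting only. For MI_30min against CT0 it recovered 94% of genes raised 2-fold and 94% of genes lowered to 0.5-fold. For Dm_90min against CT0 it recovered 98% and 84%, and for Of_30min against CT0 96% and 90%. False calls numbered 4 to 6 in each. The floor of 3 counts covers counting error only, and the labels name no molecular identifiers. Bootstrap intervals (2000 draws) were taken over the genes of a list or over gene pairs, which are not independent, and not over libraries.

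Alternatives were DESeq2 1.42.0, edgeR's RLE factors, no filter on low counts, a replicate block, a fit of only the 6 libraries compared, the other control group and each library left out in turn. For lists they were an estimated correlation, fry and the replicate block. Alternatives added after the data were seen were the mean of both controls, every transcript model, leaving out the 4 shallowest libraries, library totals without TMM factors, all libraries thinned to the shallowest, and all tested genes as the background of lists. The RefSeq gene table was not used, since its locus tags do not match the gene IDs. No coordinates are therefore given.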

Results

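Read counts per gene were compared between mycelium of T. atroviride that was injured with a scalpel, grazed by D. melanogaster larvae, grazed by O. folsomi or left untreated. Each of the 14 groups held 3 libraries. Total counts ranged from 1152096 in CT0 replicate 2 to 5398093 in replicate 2 of MI_4h. The 4 shallowest libraries were CT0 replicate 2, Dm_90min replicate 3 (1443447), Of_30min replicate 1 (1484486) and Dm_8h replicate 2 (1607248), and every other library held at least 2260001. A single gene without a product text, Tatro_002410-T1, took 16.9% of the counts in CT0 replicate 2, 12.5% in Of_30min replicate 1 and 14.9% in Dm_8h replicate 2. In CT0 replicate 3 it took 3.27%. Correlations of log2 CPM within groups were lowest in Dm_90min (0.951), Dm_8h (0.954) and CT0 (0.965), and at least 0.977 in the other groups. In the plot of principal components, injured and larva-grazed libraries lay apart from the untreated ones, while the O. folsomi libraries lay nearer to the controls. On component 2 the untreated libraries spanned -20.74 to -10.06. The O. folsomi libraries of 30 min (-31.82 to -24.72) and 4 h (-29.39 to -23.24) all lay below that range.

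**Figure D1:**
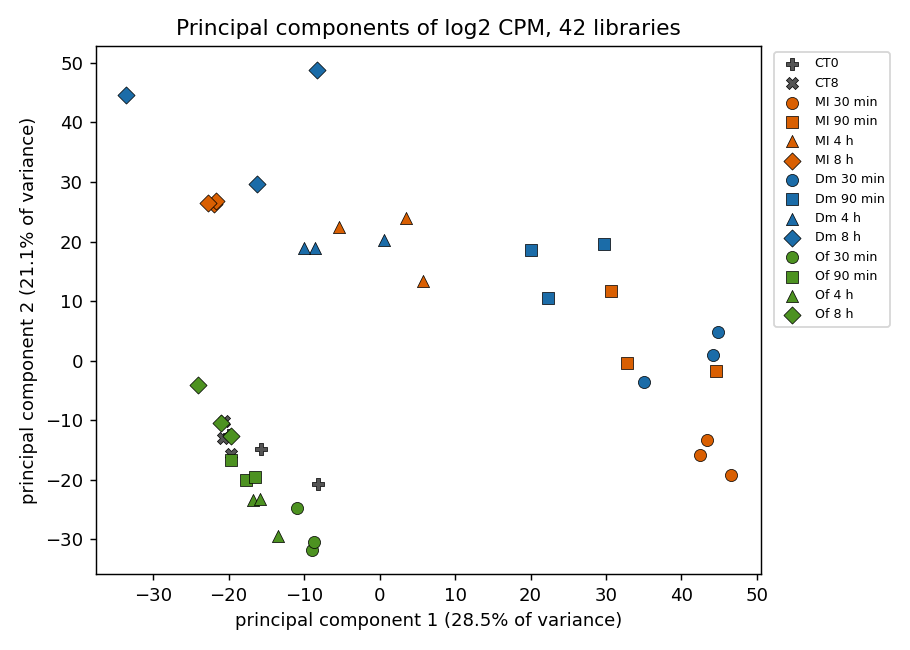
Principal components 1 (28.5% of variance) and 2 (21.1%) of log2 CPM, with 1 point per library, colour for the treatment and shape for the time. Larva-grazed libraries of 30 min lie next to injured libraries of 90 min. O. folsomi libraries lie near the untreated ones, with those of 30 min and 4 h below all of these on component 2.

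**Figure D2:**
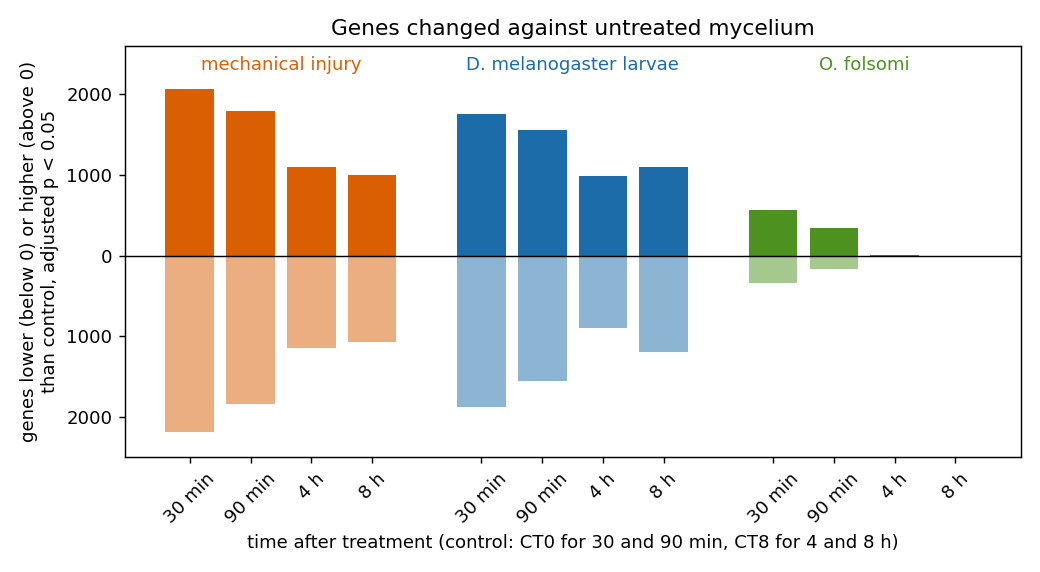
Number of genes higher (bars upwards) and lower (bars downwards) than the control at an adjusted p under 0.05, by treatment and time after treatment, with 3 libraries per group. The control is CT0 at 30 and 90 min and CT8 at 4 and 8 h. After injury the number was 2068 up and 2185 down at 30 min and 1005 up and 1066 down at 8 h. After O. folsomi it was 570 up and 340 down at 30 min and 0 at 8 h. With CT0 at all 4 times the O. folsomi counts were 910, 503, 1193 and 795. With CT8 they were 368, 3, 19 and 0. The change over time is thus not separate from the change of control.

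The first question was which transcripts change after mechanical injury. At 30 min the largest rise among the genes named by rule was that of Tatro_008185-T1, a CFEM domain protein (a cysteine-rich domain of fungal cell surface proteins). It went from 13 ± 2.93 to 1280 ± 81.1 CPM (SD, n = 3), a 91.4-fold rise. A cytochrome P450, Tatro_006595-T1, rose 85.2-fold (log2 6.41 ± 0.53, SE) and the cytochrome b5-like Tatro_006594-T1 rose 74.1-fold (log2 6.21 ± 0.57). A CoA-transferase, Tatro_003076-T1, rose by 5.98 ± 0.57 on the log2 scale, to 14 ± 1.27 CPM. These values imply a CT0 level near 0, so the size of its fold is uncertain. The largest falls included Tatro_010893-T1, of glycoside hydrolase family 28, which contains pectin-degrading polygalacturonases (log2 -4.43 ± 0.36, 21.6-fold lower), and the alpha/beta hydrolase Tatro_003167-T1 (log2 -4.25 ± 0.43). The acyl carrier protein-like genes Tatro_010804-T1 and Tatro_010807-T1 fell by 4.74 ± 0.84 and 4.24 ± 0.84 on the log2 scale. Their CT0 levels differed widely between libraries. Without CT0 replicate 2 the log2 changes were -3.40 and -2.88, and without CT0 replicate 3 they were -5.43 and -5.00.

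Ribosomal protein and ribosome biogenesis genes rose together at 30 min after injury, while the tRNA ligases were not called (median -0.03). Of 66 cytosolic and mitochondrial ribosomal protein genes, 62 rose and 4 did not pass the test, with 65 up when adjusted over the list alone. The median log2 change was 0.52 (camera adjusted p = 2.1e-05, adjusted p = 0.59 with an estimated correlation). The L10P gene Tatro_005715-T1 rose by 1.2 ± 0.21 and the L30e-like gene Tatro_001967-T1 by 1.10 ± 0.19 on the log2 scale. All 24 ribosome biogenesis genes rose, also when adjusted over the list alone (median 0.91, camera adjusted p = 0.00035, adjusted p = 0.54 with an estimated correlation). Among them the pre-rRNA processing gene Tatro_005725-T1 rose by 1.15 ± 0.18. Of 32 DNA replication and repair genes 28 rose and 4 fell, with the same counts adjusted over the list alone (median 0.63, camera adjusted p = 0.0007, adjusted p = 0.43 with an estimated correlation). Examples were a DNA polymerase alpha/epsilon subunit, Tatro_010680-T1 (1.12 ± 0.12), and the family A DNA polymerase Tatro_006868-T1 (1.21 ± 0.21). Of 19 genes of fatty acid oxidation and the glyoxylate cycle, 15 rose and 4 fell, again also when adjusted over the list alone (median 0.77, camera adjusted p = 0.017, adjusted p = 0.43 with an estimated correlation). The 3-hydroxyacyl-CoA dehydrogenase Tatro_006592-T1, an enzyme of beta-oxidation, rose 42.7-fold. Malate synthase, Tatro_001429-T1, an enzyme of the glyoxylate cycle, went from 91.3 ± 26 to 207 ± 19.7 CPM.

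Most glycoside hydrolases and peptidases fell at 30 min after injury. The lists of lipases and lipid signalling (median -0.13) and of chitinases (median -1.04) were not called. Of 44 glycoside hydrolases 34 fell, 8 rose and 2 did not pass, with 36 down and 8 up when adjusted over the list alone (median -1.05, camera adjusted p = 0.0029, adjusted p = 0.43 with an estimated correlation). The alpha-1,3-glucanase family gene Tatro_002916-T1 fell 7.1-fold, from 42.7 ± 7.55 to 6.19 ± 1.35 CPM, and the family 76 gene Tatro_001589-T1 fell 8.84-fold. Of 61 peptidases 46 fell, 12 rose and 3 did not pass, with 47 down and 13 up when adjusted over the list alone (median -0.69, camera adjusted p = 0.002, adjusted p = 0.43 with an estimated correlation). The gamma-glutamyltranspeptidase Tatro_010224-T1 fell 6.11-fold and the S53 peptidase Tatro_011153-T1 fell 4.57-fold. In edgeR's quasi-likelihood test 4253 of 9193 genes changed, 2068 up and 2185 down, and 1203 changed at least 2-fold. All list members were selected by the study from this comparison, so the counts describe directions and are not independent evidence of change.

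At 90 min after injury the CFEM gene Tatro_008185-T1 was still 30.5-fold above CT0, at 425 ± 92.4 CPM (SD, n = 3). An FAD/NAD(P)-binding domain protein, Tatro_000291-T1, rose 65.8-fold (log2 6.04 ± 0.81). Its CT0 level was near 0, so the size of this fold is uncertain. A catalase, Tatro_007179-T1, which degrades hydrogen peroxide, rose 39.8-fold (log2 5.32 ± 0.45), and a histidine-specific methyltransferase with the preceding ID number, Tatro_007178-T1, rose 31.7-fold. Tatro_010893-T1 of glycoside hydrolase family 28 fell 25.9-fold, and another CFEM gene, Tatro_000363-T1, fell 13-fold. Ribosomal protein genes rose in 64 of 66 cases and 2 did not pass, with 65 up when adjusted over the list alone (median 0.81, camera adjusted p = 5.4e-15, adjusted p = 0.52 with an estimated correlation). All 24 ribosome biogenesis genes rose, also when adjusted over the list alone (median 1.00, camera adjusted p = 2.4e-07, adjusted p = 0.52 with an estimated correlation). Among these the nucleolar complex protein 2 gene Tatro_000572-T1 rose by 1.17 ± 0.23 on the log2 scale.

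Cytoskeletal genes were among those that fell at 90 min. Of 41 genes for the cell cycle and cytoskeleton 19 fell, 6 rose and 16 did not pass, with 19 down and 8 up when adjusted over the list alone (median -0.24, camera adjusted p = 0.04, adjusted p = 0.52 with an estimated correlation). Beta tubulin, Tatro_008989-T1, went from 1730 ± 79.2 to 939 ± 85.5 CPM and the actin-depolymerising factor Tatro_005840-T1 fell by 1.00 ± 0.13 on the log2 scale. Of 79 transporters of the major facilitator superfamily (MFS) 30 fell, 12 rose and 37 did not pass, with 31 down and 13 up when adjusted over the list alone (median -0.22, camera adjusted p = 0.04, adjusted p = 0.52 with an estimated correlation). Tatro_010191-T1 fell 3.32-fold. Of 61 peptidases 24 fell, 10 rose and 27 did not pass, also when adjusted over the list alone (median -0.31, and -0.56 against CT8, camera adjusted p = 0.045, adjusted p = 0.52 with an estimated correlation). The S53 peptidase Tatro_011153-T1 fell 3.04-fold. In all 3635 genes changed, 1799 up and 1836 down, 900 of them at least 2-fold.

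At 4 h after injury, against CT8, a hydrophobin of the cerato-ulmin family appeared among the largest rises of the genes named by rule. This gene, Tatro_007246-T1, encodes a small secreted protein of a kind that coats aerial hyphae and spores. It went from 7.28 ± 2.93 to 72.8 ± 21.8 CPM (SD, n = 3, 9.82-fold). CFEM gene Tatro_008185-T1 was 9.87-fold, catalase Tatro_007179-T1 7.47-fold and methyltransferase Tatro_007178-T1 12.8-fold above CT8. Among falls were Tatro_002948-T1, with a carbohydrate-binding WSC domain (7.28-fold), and Tatro_002916-T1 of glycoside hydrolase family 71 (4.8-fold). Of 44 glycoside hydrolases 19 fell, 3 rose and 22 did not pass, with 22 down and 3 up when adjusted over the list alone (median -0.46, camera adjusted p = 0.0022, adjusted p = 0.37 with an estimated correlation). Of the cell cycle and cytoskeleton genes 15 fell, 2 rose and 24 did not pass, also when adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.37 with an estimated correlation). Against CT0 7 of these genes fell and 0 rose (median -0.13). Actin, Tatro_010755-T1, fell from 4120 ± 180 to 2300 ± 118 CPM (against CT0 the log2 change was -0.18 and not past the threshold) and alpha tubulin, Tatro_003350-T1, from 2270 ± 128 to 1450 ± 70.2. Ribosomal protein genes rose in 31 of 66 cases and 35 did not pass, with 39 up when adjusted over the list alone (median 0.39, camera adjusted p = 7.2e-10, adjusted p = 0.69 with an estimated correlation). Of ribosome biogenesis genes 8 of 24 rose, with 9 up when adjusted over the list alone (median 0.44, camera adjusted p = 0.0022, adjusted p = 0.78 with an estimated correlation). Against CT0 their median was 0.09 with 0 past the threshold in edgeR, and from CT0 to CT8 in untreated mycelium it was -0.36, with 2 of 24 down. In all 2246 genes changed, 1098 up and 1148 down, 374 of them at least 2-fold (204 up and 170 down). Without MI_4h replicate 1 the count was 1406, and with library totals in place of TMM factors the split was 1298 up and 756 down.

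At 8 h after injury the hydrophobin gene Tatro_007246-T1 was 18.4-fold above CT8, at 136 ± 27.9 CPM (SD, n = 3). A regulator of G-protein signalling, Tatro_007094-T1, rose 5.19-fold (log2 2.37 ± 0.26), and catalase Tatro_007179-T1 was 6.14-fold higher. The glucanase-like Tatro_009479-T1 fell 7.36-fold (log2 -2.88 ± 0.29) and Tatro_002167-T1, with a lysozyme-like domain, 6.21-fold. Of 44 glycoside hydrolases 18 fell, 4 rose and 22 did not pass, with 20 down and 7 up when adjusted over the list alone (median -0.30, camera adjusted p = 0.035, adjusted p = 0.59 with an estimated correlation). No other list was called at this time. In all 2071 genes changed, 1005 up and 1066 down, 396 of them at least 2-fold (279 up and 117 down). Without CT8 replicate 1 the count was 1360, and with library totals alone the split was 1453 up and 493 down, with the median of all genes shifted by 0.121 on the log2 scale.

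**Figure D3:**
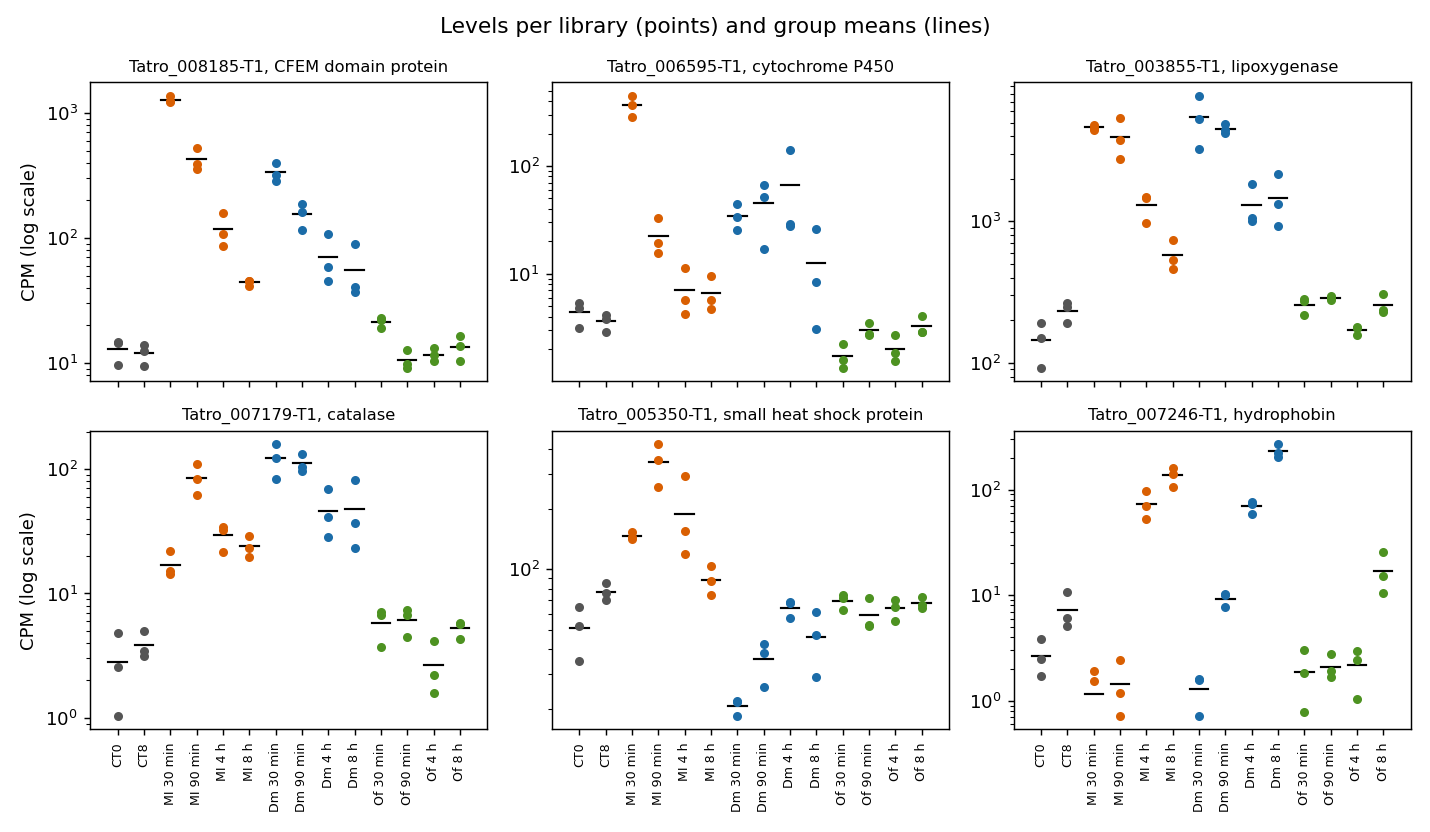
CPM per library (points, log scale) and group means (lines, n = 3) of 6 genes in the 14 groups, with a single library at 0 CPM (hydrophobin, MI 30 min) outside the axis. The CFEM gene was highest at 30 min after injury (1280 CPM), lipoxygenase (Tatro_003855-T1) rose after injury and larvae and had means of 171 to 288 CPM after O. folsomi, and the hydrophobin was highest at 8 h after larvae (232 CPM).

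The second question was which transcripts change after grazing by D. melanogaster larvae. At 30 min Tatro_000291-T1, with an FAD/NAD(P)-binding domain, rose from 0.494 ± 0.444 to 111 ± 97 CPM (SD, n = 3), a log2 change of 7.32 ± 0.76. Without Dm_30min replicate 1 the log2 change was 6.34. The MFS transporter Tatro_002316-T1 rose 60.6-fold, to a mean of 36.3 CPM. These values imply a CT0 level near 0, so the size of its fold is uncertain. Catalase Tatro_007179-T1 rose 56.5-fold. A lipoxygenase, Tatro_003855-T1, of the enzymes that oxidise polyunsaturated fatty acids, went from 144 ± 49 to 5430 ± 2220 CPM (38.7-fold). Tatro_010893-T1 of glycoside hydrolase family 28 fell 35-fold (log2 -5.13 ± 0.38). A group of genes with close ID numbers fell as well. The acyl carrier protein-like Tatro_010804-T1 changed by -5.96 ± 0.96 and the Cys/Met metabolism gene Tatro_010808-T1 by -4.95 ± 0.80 on the log2 scale. Without CT0 replicate 2 these were -4.61 and -3.99, and without CT0 replicate 3 they were -6.64 and -5.54. For Tatro_010808-T1 the change was -5.61 without Dm_30min replicate 2.

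Ribosomal protein genes rose in 65 of 66 cases at 30 min after larvae, also when adjusted over the list alone (median 0.82, camera adjusted p = 6.8e-16, adjusted p = 0.6 with an estimated correlation). The L10P gene Tatro_005715-T1 rose by 1.43 ± 0.21 on the log2 scale. All 24 ribosome biogenesis genes rose, also when adjusted over the list alone (median 1.02, camera adjusted p = 1e-07, adjusted p = 0.6 with an estimated correlation), such as the Nop53 gene Tatro_003424-T1 (1.3 ± 0.16). Of 79 MFS transporters 33 fell, 13 rose and 33 did not pass, with 40 down and 15 up when adjusted over the list alone (median -0.37, camera adjusted p = 0.023, adjusted p = 0.56 with an estimated correlation). Tatro_000360-T1 fell 3.76-fold. Of 61 peptidases 33 fell, 10 rose and 18 did not pass, with 35 down and 10 up when adjusted over the list alone (median -0.42, and -0.68 against CT8, camera adjusted p = 0.023, adjusted p = 0.6 with an estimated correlation). The cysteine peptidase Tatro_011504-T1 fell 2.6-fold. In all 3634 genes changed, 1760 up and 1874 down, 905 of them at least 2-fold.

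At 90 min after larvae Tatro_000291-T1, with an FAD/NAD(P)-binding domain, stood at 103 ± 26.7 CPM (SD, n = 3, log2 7.18 ± 0.77), catalase Tatro_007179-T1 was 50.5-fold and lipoxygenase Tatro_003855-T1 32.1-fold above CT0. The acyl carrier protein-like gene Tatro_010804-T1 had 0 counts in all 3 libraries, against 28.9 ± 35.9 CPM in CT0, where libraries ranged from 4.51 to 70.1, the highest being replicate 2. Against a floor of 3 counts over the group (0.31 CPM) it was at least 93.5-fold lower than the CT0 mean, at least 27-fold lower than the CT0 mean without replicate 2 (8.37 CPM) and at least 12.2-fold lower than CT8 (3.77 CPM). The alpha/beta hydrolase Tatro_006355-T1 fell 84.1-fold (log2 -6.39 ± 0.61, and -7.34 without Dm_90min replicate 2) and the CFEM gene Tatro_000363-T1 64.3-fold, from 429 ± 129 to 6.72 ± 1.25 CPM. Ribosomal protein genes rose in 62 of 66 cases, with 63 up when adjusted over the list alone (median 0.99, camera adjusted p = 2.2e-22, adjusted p = 0.34 with an estimated correlation). Of ribosome biogenesis genes 15 of 24 rose, with 17 up when adjusted over the list alone (median 0.54, and 0.84 against CT8, camera adjusted p = 0.0013, adjusted p = 0.64 with an estimated correlation). Among them Tatro_002216-T1, a pre-rRNA processing gene, rose by 0.78 ± 0.17. Of 15 tRNA ligases 6 rose, 1 fell and 8 did not pass, with 8 up and 1 down when adjusted over the list alone (median 0.28, camera adjusted p = 0.031, adjusted p = 0.4 with an estimated correlation). The class II synthetase gene Tatro_000081-T1 rose by 0.79 ± 0.12.

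In 5 further lists called at 90 min after larvae, more members fell than rose. Of the 19 fatty acid oxidation and glyoxylate cycle genes 12 fell, 2 rose and 5 did not pass, also when adjusted over the list alone (median -0.48, camera adjusted p = 0.011, adjusted p = 0.34 with an estimated correlation). Malate synthase, Tatro_001429-T1, went from 91.3 ± 26 to 36.9 ± 5.15 CPM. Of 44 glycoside hydrolases 18 fell, 5 rose and 21 did not pass, with 20 down and 7 up when adjusted over the list alone (median -0.32, camera adjusted p = 0.012, adjusted p = 0.34 with an estimated correlation). Tatro_010233-T1 fell 5.28-fold. Of 79 MFS transporters 23 fell, 10 rose and 46 did not pass, with 26 down and 10 up when adjusted over the list alone (median -0.26, camera adjusted p = 0.0041, adjusted p = 0.21 with an estimated correlation). Tatro_007953-T1 fell 2.5-fold. Of 95 transcription factors, zinc cluster proteins included, 18 fell, 9 rose and 68 did not pass, also when adjusted over the list alone (median -0.13, camera adjusted p = 0.017, adjusted p = 0.51 with an estimated correlation). Against all tested genes the call ended (camera adjusted p = 0.074). Tatro_006936-T1 went from 658 ± 39.4 to 274 ± 25.5 CPM. Of 41 cell cycle and cytoskeleton genes 8 fell, 2 rose and 31 did not pass, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.031, adjusted p = 0.34 with an estimated correlation), and this call too ended against all tested genes (camera adjusted p = 0.082). The kinesin Tatro_008551-T1 fell 1.68-fold. In all 3114 genes changed, 1555 up and 1559 down, 753 of them at least 2-fold (416 up and 337 down). A fit of only the 6 libraries compared gave 1274, and with library totals alone the split was 1036 up and 2068 down, the median of all genes shifting by -0.127 on the log2 scale.

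At 4 h after larvae the methyltransferase Tatro_007178-T1 was 18-fold and catalase Tatro_007179-T1 11.5-fold above CT8. The cytochrome P450 Tatro_006595-T1 stood at 66.3 ± 65.7 CPM (SD, n = 3) against 3.61 ± 0.678 in CT8 (log2 4.11 ± 0.54). Without Dm_4h replicate 2 its log2 change was 2.94, and that of the cytochrome b5-like Tatro_006594-T1 went from 4.02 to 2.96. An aldolase-type protein, Tatro_002727-T1, fell 20.8-fold (log2 -4.38 ± 0.43, and -5.61 without Dm_4h replicate 3), and the CFEM gene Tatro_000363-T1 fell 8.8-fold. Of 44 glycoside hydrolases 21 fell, 2 rose and 21 did not pass, with 23 down and 2 up when adjusted over the list alone (median -0.49, camera adjusted p = 5.8e-05, adjusted p = 0.12 with an estimated correlation). The family 47 gene Tatro_004830-T1 fell from 99.2 ± 21.2 to 14.2 ± 3.19 CPM. Of 66 ribosomal protein genes 17 rose and 49 did not pass, also when adjusted over the list alone (median 0.22, camera adjusted p = 0.00043, adjusted p = 0.97 with an estimated correlation). Against CT0 the median was 0.17, with 1 up. In all 1888 genes changed, 989 up and 899 down, 402 of them at least 2-fold. Against CT0 in place of CT8 the count was 1025.

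At 8 h after larvae the hydrophobin Tatro_007246-T1 reached 232 ± 32.6 CPM (SD, n = 3), 31.1-fold above CT8 (log2 4.96 ± 0.27). A cytochrome P450, Tatro_001233-T1, rose from 75.9 ± 4.32 to 570 ± 79.2 CPM, and the methyltransferase Tatro_007178-T1 was 24.3-fold higher. Tatro_002916-T1 of glycoside hydrolase family 71 fell 7.24-fold (log2 -2.86 ± 0.32), and Tatro_001177-T1, with an NAD(P)-binding domain, changed by -2.48 ± 0.35 on the log2 scale. Without Dm_8h replicate 3 the latter were -3.45 and -4.46. Of 44 glycoside hydrolases 19 fell, 3 rose and 22 did not pass, with 21 down and 4 up when adjusted over the list alone (median -0.40, camera adjusted p = 0.0017, adjusted p = 0.39 with an estimated correlation). In all 2290 genes changed, 1096 up and 1194 down, 578 of them at least 2-fold (370 up and 208 down). The majority turned with the scaling, to 1173 up and 1098 down with RLE factors and 1187 up and 868 down with library totals alone. A fit of only the 6 libraries compared gave 1444.

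**Figure D4:**
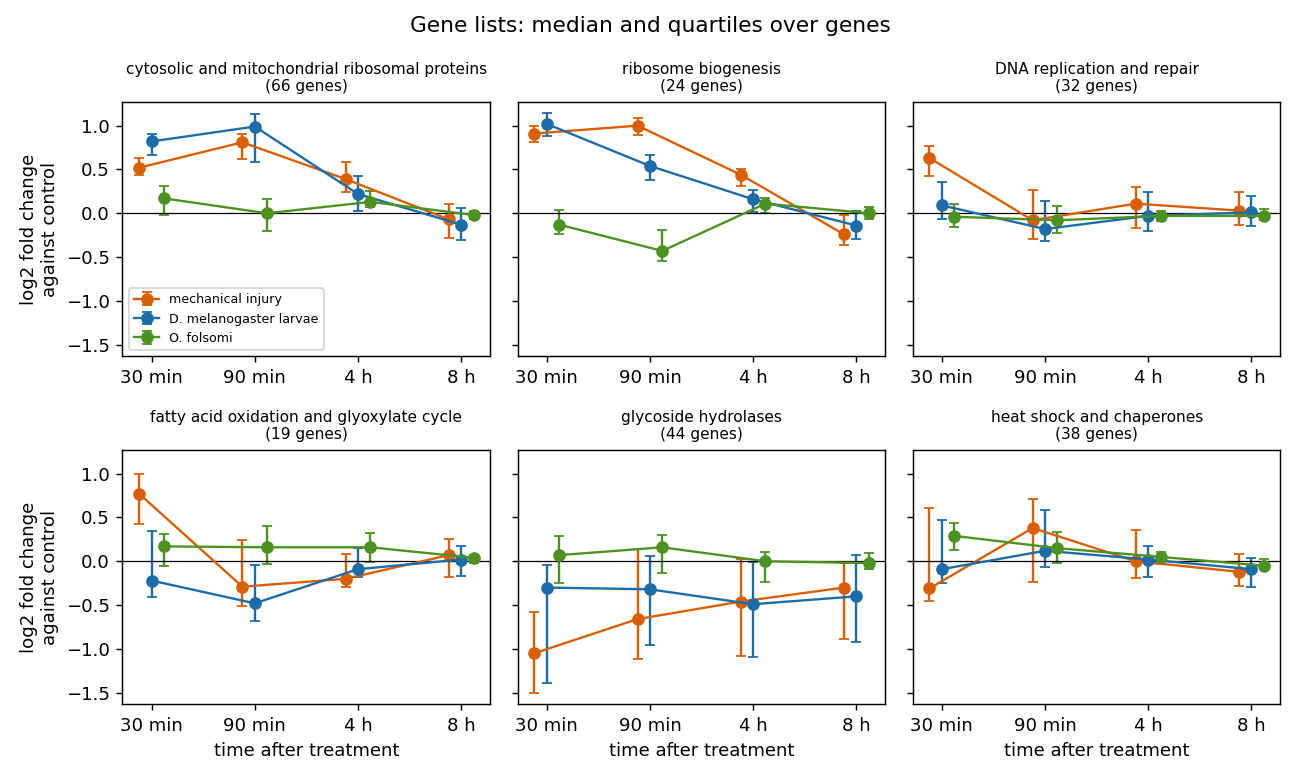
Median log2 fold change against the control (points) and quartiles over genes (bars) of 6 gene lists by time after treatment, for injury, larvae and O. folsomi. At 30 min the DNA replication and repair median was 0.63 after injury and 0.09 after larvae, and that of fatty acid oxidation was 0.77 and -0.22. All members are genes that the study called at 30 min after injury.

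The third question was whether grazing by O. folsomi changes transcript levels. At 30 min the aspartic peptidase Tatro_008494-T1 rose from 50.3 ± 15 to 189 ± 26.4 CPM (SD, n = 3, log2 1.98 ± 0.35), and against CT8 its log2 change was 1.88. Glycoside hydrolase family 28 gene Tatro_010893-T1 fell 4.4-fold (log2 -2.14 ± 0.31, and -1.22 against CT8). The Hsp90 gene Tatro_010407-T1 rose 2.14-fold and the Hsp70 gene Tatro_003383-T1 2.08-fold against CT0, but against CT8 their log2 changes were -0.47 and -0.43. Of 38 heat shock and chaperone genes 13 rose and 25 did not pass, with 16 up when adjusted over the list alone (median 0.29, camera adjusted p = 2.4e-06, adjusted p = 0.075 with an estimated correlation). In untreated mycelium 11 of the same 38 rose from CT0 to CT8, and against CT8 the median was 0.10, with 0 up and 2 down. Of 15 tRNA ligases 4 rose and 11 did not pass, with 7 up when adjusted over the list alone (median 0.28, camera adjusted p = 0.0051, adjusted p = 0.28 with an estimated correlation). The class I synthetase gene Tatro_002789-T1 rose by 0.85 ± 0.14. From CT0 to CT8 the median of the tRNA ligases was 0.19, and against CT8 it was 0.10, with 1 up. Of 66 ribosomal protein genes 8 rose and 58 did not pass, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.022, adjusted p = 0.82 with an estimated correlation). The S5 domain gene Tatro_003097-T1 rose by 0.57 ± 0.14 (0.35 and not past the threshold against CT8, where 0 of the 66 passed).

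In all 910 genes changed at 30 min after O. folsomi, 570 up and 340 down, 133 of them at least 2-fold (31 up and 102 down). Against CT8 the count was 368, 127 up and 241 down, and 135 genes were called in the same direction against both controls. With library totals alone the split was 164 up and 844 down, with the median of all genes shifted by -0.170 on the log2 scale. The count was 438 without Of_30min replicate 2, 445 without Of_30min replicate 3, 560 without Of_30min replicate 1 and 546 without CT0 replicate 3.

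At 90 min after O. folsomi the Hsp90 gene Tatro_010407-T1 was 2.62-fold above CT0 (log2 1.39 ± 0.25), the Hsp70 gene Tatro_003383-T1 2.46-fold (1.3 ± 0.19) and a CS domain gene, Tatro_006408-T1, 2.4-fold (1.26 ± 0.14). Against CT8 these changes were -0.18, -0.19 and -0.15 and not past the threshold. Of 38 heat shock genes 10 rose and 28 did not pass, with 12 up when adjusted over the list alone (median 0.15, camera adjusted p = 0.0027, adjusted p = 0.41 with an estimated correlation). Of 14 antioxidant enzymes 5 rose and 9 did not pass, with 6 up when adjusted over the list alone (median 0.38, camera adjusted p = 0.015, adjusted p = 0.36 with an estimated correlation). The catalase Tatro_008157-T1 rose by 0.68 ± 0.12 on the log2 scale, and its change against CT8 was -0.04. Of 61 peptidases 11 rose and 50 did not pass, with 13 up and 2 down when adjusted over the list alone (median 0.20, camera adjusted p = 0.025, adjusted p = 0.44 with an estimated correlation). A signal peptidase subunit, Tatro_006037-T1, rose by 0.78 ± 0.13 (0.02 against CT8). Ribosome biogenesis genes had a median of -0.43, with none of 24 past the threshold by edgeR and 7 down when adjusted over the list alone (camera adjusted p = 0.0027, adjusted p = 0.68 with an estimated correlation). From CT0 to CT8 in untreated mycelium the medians of these lists were 0.18 for heat shock, 0.45 for antioxidant enzymes, 0.12 for peptidases and -0.36 for ribosome biogenesis. Against CT8 the medians after O. folsomi were -0.03, -0.05, 0.03 and -0.02, with 0 members past the threshold in edgeR. In all 503 genes changed, 342 up and 161 down, 57 of them at least 2-fold (24 up and 33 down). Against CT8 3 genes changed, and with library totals alone the split was 165 up and 192 down. The count was 203 without CT0 replicate 3, 243 without Of_90min replicate 2, 311 without Of_90min replicate 1, 326 without Of_90min replicate 3 and 770 without the 4 shallow libraries.

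At 4 h after O. folsomi 19 genes changed against CT8, 2 up and 17 down, 14 of them at least 2-fold. Those up with a product text were an ATPase F0 complex subunit, Tatro_000931-T1 (log2 0.77 ± 0.17), and a glucose/ribitol dehydrogenase, Tatro_006082-T1 (0.57 ± 0.12). A fungal transcription factor, Tatro_004118-T1, fell from 255 ± 25 to 100 ± 7.68 CPM (SD, n = 3) (log2 -1.35 ± 0.28). Tatro_000931-T1 lost its call without each single library of both groups, CT8 replicate 2 included, at log2 changes of 0.71 to 0.81. Tatro_006082-T1 (0.51 to 0.61) and Tatro_004118-T1 (-1.40 to -1.30) lost theirs without each library except CT8 replicate 2. Cytochrome P450 genes had a median of -0.23 (25 genes, camera adjusted p = 0.0055, adjusted p = 0.21 with an estimated correlation) and incompatibility and NLR-like genes of -0.16 (23 genes, camera adjusted p = 0.016, adjusted p = 0.49 with an estimated correlation). Ribosomal protein genes had a median of 0.13 (camera adjusted p = 9.8e-06, adjusted p = 0.69 with an estimated correlation). Against CT0 these medians were -0.19, -0.03 and 0.08. Against CT8 no member of these lists passed the threshold singly in edgeR, and adjusted over the list alone only 2 P450 genes did, both down. The count of 19 was 0 without Of_4h replicate 2, 1 without Of_4h replicate 1, 4 without Of_4h replicate 3, 4 without CT8 replicate 1 and 3 without CT8 replicate 3. DESeq2 called 52 genes, a fit of only the 6 libraries compared called 672 and a comparison with CT0 1193. Of the 19 genes, 6 (31.6%, all down) were also called in the same direction against CT0.

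At 8 h after O. folsomi edgeR called 0 genes against CT8, with 118 at an unadjusted p under 0.05, and DESeq2 called 0, with 89 at an unadjusted p under 0.05. The MAP kinase genes Tatro_005384-T1, Tatro_003677-T1 and Tatro_000708-T1 had log2 changes of 0.01 ± 0.09, -0.03 ± 0.08 and -0.05 ± 0.09, and no list was called. Against CT0 the count was 795. The hydrophobin Tatro_007246-T1, which was chosen after its values were seen, stood at 17 ± 7.68 CPM (SD, n = 3) beside 7.28 ± 2.93 in CT8.

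Larval grazing and injury were then compared directly. At 30 min catalase Tatro_007179-T1 was 7.02-fold higher after larvae than after injury, at 122 ± 37.3 against 17.1 ± 4.15 CPM (SD, n = 3), and methyltransferase Tatro_007178-T1 5.87-fold higher. The P450 Tatro_006595-T1 and cytochrome b5-like Tatro_006594-T1 were each 10.7-fold lower, a fungal transcription factor, Tatro_006115-T1, 10.5-fold lower (log2 -3.39 ± 0.28) and the acyl carrier protein-like Tatro_009186-T1 11.3-fold lower. Of 32 DNA replication and repair genes 19 were lower, 2 higher and 11 did not pass, with 21 lower and 2 higher when adjusted over the list alone (median -0.54, camera adjusted p = 4e-05, adjusted p = 0.29 with an estimated correlation). The MutS-like mismatch repair genes Tatro_005197-T1 and Tatro_000410-T1 were 2-fold and 1.93-fold lower. Of 19 fatty acid oxidation and glyoxylate cycle genes 13 were lower, 2 higher and 4 did not pass, with 14 lower and 2 higher when adjusted over the list alone (median -0.75, camera adjusted p = 4e-05, adjusted p = 0.19 with an estimated correlation). Malate synthase Tatro_001429-T1 stood at 57.8 ± 16.3 against 207 ± 19.7 CPM, and the peroxisome proliferation factor Tatro_009006-T1 was 2.53-fold lower. All list members were selected by the study on these injury libraries, where 28 of the 32 and 15 of the 19 genes rose against CT0. Lower values after larvae may thus be partly built in, and the list counts and p-values of this comparison are not independent evidence. Of 95 transcription factors 39 were lower, 13 higher and 43 did not pass, with 41 lower and 14 higher when adjusted over the list alone (median -0.21, camera adjusted p = 0.013, adjusted p = 0.39 with an estimated correlation). The C2H2 zinc finger gene Tatro_002233-T1 was 5.43-fold lower. Of 66 ribosomal protein genes 15 were higher and 51 did not pass, with 14 higher when adjusted over the list alone (median 0.25, camera adjusted p = 0.02, adjusted p = 0.81 with an estimated correlation). In all 2882 genes differed, 1436 higher and 1446 lower after larvae, 711 of them at least 2-fold. With library totals alone the split was 1069 higher and 1579 lower, and with RLE factors 1453 and 1416. With all libraries thinned to the shallowest the count was 1834.

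At 90 min 3 genes of the alpha crystallin/Hsp20 family were the largest differences down among the genes named by rule. They encode small heat shock proteins that bind unfolded proteins. Tatro_005350-T1 stood at 35.5 ± 8.65 CPM after larvae and 343 ± 82.5 after injury (SD, n = 3, 10.1-fold lower), Tatro_002501-T1 was 9.86-fold lower and Tatro_009930-T1 9.82-fold. In CT0 the level of Tatro_005350-T1 was 50.6 ± 15.2 CPM. The C2H2 zinc finger gene Tatro_002233-T1 was 6.62-fold lower. Upwards, a HAD hydrolase, Tatro_009763-T1, was 3.93-fold higher (log2 1.98 ± 0.36). Of 15 glutathione S-transferases, detoxifying enzymes, 8 were higher and 7 did not pass, with 9 higher when adjusted over the list alone (median 0.41, camera adjusted p = 0.0019, adjusted p = 0.13 with an estimated correlation). Tatro_010783-T1 was 2.28-fold higher. Of 14 antioxidant enzymes 5 were higher and 9 did not pass, with 6 higher when adjusted over the list alone (median 0.33, camera adjusted p = 0.0051, adjusted p = 0.13 with an estimated correlation). Catalase Tatro_008157-T1 was 1.65-fold higher. Of 61 peptidases 13 were higher, 3 lower and 45 did not pass, with 17 higher and 4 lower when adjusted over the list alone (median 0.26, camera adjusted p = 0.0042, adjusted p = 0.26 with an estimated correlation). Of 16 amino acid synthesis genes 5 were higher and 11 did not pass, with 7 higher when adjusted over the list alone (median 0.31, camera adjusted p = 0.0043, adjusted p = 0.16 with an estimated correlation). Chorismate mutase Tatro_003634-T1 was 1.66-fold higher.

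Lower at 90 min after larvae than after injury were 9 of 24 ribosome biogenesis genes, and 15 did not pass, with 16 lower when adjusted over the list alone (median -0.49, camera adjusted p = 0.0012, adjusted p = 0.62 with an estimated correlation). The pre-rRNA processing gene Tatro_005725-T1 differed by -0.82 ± 0.18 on the log2 scale, and by -0.51, not past the threshold, without MI_90min replicate 1. Of 8 small secreted and surface proteins 3 were lower and 5 did not pass, with 4 lower when adjusted over the list alone (median -0.53, camera adjusted p = 0.015, adjusted p = 0.23 with an estimated correlation). Those were the CFEM genes Tatro_008185-T1 (2.8-fold) and Tatro_000302-T1 (1.57-fold) and the ADAM cysteine-rich gene Tatro_008304-T1 (1.47-fold). The log2 difference of the last, -0.56 ± 0.17, lost its call at -0.58 without MI_90min replicate 1, -0.56 without MI_90min replicate 2, -0.51 without MI_90min replicate 3 and -0.36 without Dm_90min replicate 3. Of 95 transcription factors 13 were lower, 3 higher and 79 did not pass, with 15 lower and 3 higher when adjusted over the list alone (median -0.06, camera adjusted p = 0.021, adjusted p = 0.62 with an estimated correlation). Tatro_008187-T1 was 2.64-fold lower. In all 1078 genes differed, 619 higher and 459 lower, 187 of them at least 2-fold. The count was 360 without MI_90min replicate 1, 643 without Dm_90min replicate 3 and 77 in a fit of only the 6 libraries, and with library totals alone the split was 344 higher and 599 lower.

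At 4 h the ankyrin repeat gene Tatro_000365-T1 was 3.92-fold higher after larvae than after injury, at 170 ± 18.9 CPM (SD, n = 3), and the Hsp70 gene Tatro_000891-T1 3.88-fold. The small heat shock gene Tatro_005350-T1 was 2.94-fold lower and Tatro_002501-T1 4.57-fold lower (log2 -2.19 ± 0.36, and -1.51 without MI_4h replicate 2). The P450 Tatro_006595-T1 differed by 3.14 ± 0.47 on the log2 scale, and by 1.98 without Dm_4h replicate 2. Of 41 cell cycle and cytoskeleton genes 4 were higher and 37 did not pass, with 6 higher when adjusted over the list alone (median 0.17, camera adjusted p = 0.017, adjusted p = 0.24 with an estimated correlation). Of 22 ubiquitin and proteasome genes 1 was higher, with 2 higher when adjusted over the list alone (median 0.14, camera adjusted p = 0.021, adjusted p = 0.24 with an estimated correlation). This was Tatro_002852-T1, by 0.61 ± 0.14, and by 0.44, not past the threshold, without MI_4h replicate 1. Of 19 fatty acid oxidation genes 3 were higher, with 6 higher and 1 lower when adjusted over the list alone (median 0.20, camera adjusted p = 0.021, adjusted p = 0.31 with an estimated correlation). Peroxin-3, Tatro_008647-T1, was higher by 0.42 ± 0.10 and lost its call without MI_4h replicate 1 (0.34). Ribosomal protein genes had a median of -0.18 (camera adjusted p = 0.0017, adjusted p = 0.69 with an estimated correlation) and ribosome biogenesis genes of -0.23 (camera adjusted p = 0.037, adjusted p = 0.69 with an estimated correlation), with no member past the threshold in edgeR, also when adjusted over the list alone. In all 562 genes differed, 358 higher and 204 lower, 146 of them at least 2-fold. The count was 201 without MI_4h replicate 1, 241 without Dm_4h replicate 1, 311 without Dm_4h replicate 3 and 283 at a common depth, and with library totals alone the split was 193 higher and 291 lower.

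At 8 h an ankyrin repeat gene, Tatro_006439-T1, was 4.22-fold higher after larvae (76.1 ± 31.3 against 18.4 ± 3.71 CPM, SD, n = 3), and its neighbour in ID number Tatro_006438-T1, a berberine-like oxidoreductase, 2.96-fold. The MFS transporter Tatro_007357-T1 was 1.97-fold lower. A cyclopropane synthase-like gene, Tatro_002107-T1, was 3.01-fold higher. Of 79 MFS transporters 2 were lower and 77 did not pass, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.033, adjusted p = 0.36 with an estimated correlation), and the call ended against all tested genes (camera adjusted p = 0.063). In all 139 genes differed, 84 higher and 55 lower, 58 of them at least 2-fold. The count was 39 without MI_8h replicate 2, 54 without MI_8h replicate 3, 63 without Dm_8h replicate 1, 449 without Dm_8h replicate 3, 81 at a common depth and 11 in a fit of only the 6 libraries. With library totals alone the split was 50 higher and 64 lower.

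The grazers were compared at the same time without a control. Genes for this comparison were chosen after their values were seen, from those named above. Lipoxygenase Tatro_003855-T1 was higher after larvae than after O. folsomi by 4.39 ± 0.31, 3.97 ± 0.30, 2.92 ± 0.29 and 2.51 ± 0.28 on the log2 scale from 30 min to 8 h. Catalase Tatro_007179-T1 was higher by 4.46 ± 0.40, 4.16 ± 0.38, 4.11 ± 0.44 and 3.05 ± 0.40, and CFEM gene Tatro_008185-T1 by 3.98 ± 0.28, 3.83 ± 0.31, 2.55 ± 0.30 and 1.96 ± 0.31. Hydrophobin Tatro_007246-T1 was higher by 5.0 ± 0.34 at 4 h and 3.79 ± 0.24 at 8 h. Tatro_010893-T1 of glycoside hydrolase family 28 was lower, by -2.99 ± 0.49 at 30 min and -4.02 ± 0.47 at 90 min. In all 3804 genes differed at 30 min (1864 higher and 1940 lower after larvae), 3160 at 90 min (1587 and 1573), 2410 at 4 h (1233 and 1177) and 2023 at 8 h (982 and 1041). With library totals alone the split at 30 min was 2290 higher and 1392 lower, the median of all genes shifting by 0.102. A fit of only the 6 libraries gave 1883 genes at 90 min and 1126 at 8 h, and at a common depth the counts were 1432 at 4 h and 1347 at 8 h.

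The controls themselves differed. From CT0 to CT8 the Hsp90 gene Tatro_010407-T1 rose by 1.57 ± 0.25 on the log2 scale and the Hsp70 gene Tatro_003383-T1 by 1.49 ± 0.19. In CT0 replicate 3 these stood at 236 and 473 CPM, and in the other CT0 libraries at 777 to 855 and 1065 to 1144. The CS domain gene Tatro_006408-T1 rose by 1.42 ± 0.14 and a D-amino acid oxidase, Tatro_002910-T1, by 1.98 ± 0.41, while the glucose/ribitol dehydrogenase Tatro_011861-T1 fell by 1.98 ± 0.17. These genes were chosen after their values were seen. Of 38 heat shock and chaperone genes 11 rose. In all 773 genes differed, 468 higher and 305 lower in CT8, 109 of them at least 2-fold. The count was 386 without CT0 replicate 3, 414 without CT8 replicate 1, 426 without CT8 replicate 3 and 390 at a common depth.

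MAP kinases are part of the known injury signalling of this fungus. Product texts identified a MAP kinase kinase kinase, Tatro_005384-T1, and the MAP kinases Tatro_003677-T1 and Tatro_000708-T1. Tatro_005384-T1 rose at 30 min after injury by 0.38 ± 0.09 on the log2 scale (0.680 against CT8) and was lower by -0.35 ± 0.09 after larvae than after injury. It fell by 0.34 ± 0.09 at 90 min after larvae and by 0.31 ± 0.09 at 30 min and 0.32 ± 0.09 at 90 min after O. folsomi. Against CT8 these were -0.048, -0.016 and -0.028 and not past the threshold. The fall at 30 min after O. folsomi lost its call without each library of both groups except Of_30min replicate 1 (-0.32 to -0.26), and that at 90 min without each except Of_90min replicate 3 (-0.34 to -0.28). At 8 h after injury it rose by 0.24 ± 0.09 (-0.055 against CT0), a call lost without each library of both groups except MI_8h replicate 3 (0.18 to 0.27). Tatro_003677-T1 rose by 0.32 ± 0.09 at 90 min after injury, 0.47 ± 0.09 after larvae and 0.54 ± 0.09 after O. folsomi against CT0. Against CT8 these were -0.32, -0.17 and -0.09. At 30 min after O. folsomi it rose by 0.36 ± 0.09 (-0.271 against CT8), a call lost at 0.32 without CT0 replicate 3 and 0.33 without Of_30min replicate 2. At 4 h after larvae it fell by 0.34 ± 0.09 (0.295 against CT0), a call lost at -0.27 without Dm_4h replicate 1. Tatro_000708-T1 fell by 0.44 ± 0.09 at 4 h after injury and by 0.35 ± 0.09 at 4 h after larvae (-0.111 and -0.025, not past the threshold, against CT0). At 90 min it fell by 0.24 ± 0.09 after injury (also past the threshold against CT8), rose by 0.30 ± 0.09 after O. folsomi (-0.028 against CT8) and was higher by 0.28 ± 0.09 after larvae than after injury. The fall was lost without CT0 replicates 2 and 3 (-0.20 and -0.24) and MI_90min replicates 1 and 2 (-0.17 and -0.24). The rise was lost without each library of both groups except CT0 replicate 2 (0.24 to 0.36). The difference was lost without MI_90min replicates 1 and 2 (0.23 and 0.28) and Dm_90min replicates 1 and 3 (0.29 and 0.22).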

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

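The genes and the gene list described in this part were chosen after the result was seen. At 30 min the directions after injury and after larvae differed for part of the genes, by a test of the difference itself (larvae against injury, adjusted p under 0.05). Of 2465 genes called in both comparisons with CT0, 72 rose after injury and fell after larvae, and 76 fell after injury and rose after larvae. DESeq2 gave 60 and 68, and 33 and 34 also differed in direction against CT8. The alternative oxidase Tatro_007421-T1 had log2 changes of 1.18 after injury and -1.18 after larvae, and the fungal transcription factor Tatro_006115-T1 of 2.52 and -0.88. Malate synthase, Tatro_001429-T1, had 1.25 and -0.60, and isocitrate lyase, Tatro_011916-T1, 0.76 and -0.43. The last pair are enzymes of the glyoxylate cycle.

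Of the 58 genes with a product text that fell after injury and rose after larvae at 30 min, 24 belong to a list of 31 genes drawn up by words in the texts after these values were seen. Its words were those of signal peptidase, Sec translocation, oligosaccharyl transferase, calnexin and disulphide isomerase texts, among others. It also took in texts that name broader or other functions, such as the GOLD domain of Tatro_006071-T1, glycosyl transferase family 39/83 of Tatro_007591-T1, an endoplasmic reticulum vesicle transporter, Tatro_002065-T1, and the S24/S26 peptidase domain of Tatro_008481-T1. The list was made from these values, so no test of it is given for injury and larvae at 30 min, where its direction was fixed by the choice. The product texts were also given by the study for genes called on the same samples. Calnexin, Tatro_008807-T1, had log2 changes of -0.89 at 30 min after injury and 0.67 after larvae. The translocation protein gene Tatro_004030-T1 had -0.49 and 0.79, the disulphide isomerase Tatro_009798-T1 -0.41 and 0.81, and the signal peptidase subunit Tatro_011735-T1 -0.65 and 0.88. Over the 31 genes, medians against CT0 at 30 min were -0.57 after injury (30 down) and 0.47 after larvae (25 up). Against CT8 they were -0.88 (31 down) and 0.16 (12 up and 1 down), so the rise after larvae depended largely on the control. Between Dm_30min and MI_90min 0 of the 31 differed (median -0.01). In comparisons that did not enter the choice, though against the same CT0 libraries, 25 of the 31 rose at 90 min after injury (median 0.46, camera adjusted p = 1.7e-06, adjusted p = 0.13 with an estimated correlation). Against CT8 13 rose and 1 fell (median 0.14, camera adjusted p = 0.023, adjusted p = 0.35 with an estimated correlation). At 30 min after O. folsomi 14 rose against CT0 (median 0.30, camera adjusted p = 5.5e-08, adjusted p = 0.037 with an estimated correlation). Against CT8 none of the 31 passed the threshold in edgeR and the list was not called (median 0.07, camera adjusted p = 0.062, adjusted p = 0.44 with an estimated correlation), and 8 rose from CT0 to CT8 in untreated mycelium (median 0.22). At 90 min after larvae 19 rose against CT0 (median 0.38, camera adjusted p = 2.1e-05, adjusted p = 0.21 with an estimated correlation). Against CT8 11 rose, 4 fell and the list was not called (median 0.10, camera adjusted p = 0.21). At 90 min after O. folsomi 9 rose against CT0 (median 0.24, camera adjusted p = 9.7e-07, adjusted p = 0.12 with an estimated correlation). Against CT8 0 of the 31 passed (median 0.00, camera adjusted p = 0.47).

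At the later times few genes differed in direction. At 90 min 1 gene rose after injury and fell after larvae, the Hsp20 gene Tatro_009930-T1 (2.14 and -1.15). The 4 that fell after injury and rose after larvae were cyanate hydratase, Tatro_009945-T1 (-0.65 and 0.48), Tatro_000867-T1, a methyltransferase (-0.63 and 0.59), Tatro_006034-T1 (-0.28 and 0.31) and Tatro_010579-T1 (-0.30 and 0.29). Against CT8 the Hsp20 gene and cyanate hydratase passed again in these directions, while the changes after larvae were 0.04, 0.24 and -0.22 for Tatro_000867-T1, Tatro_006034-T1 and Tatro_010579-T1 and not past the threshold. At 4 h 0 genes rose after injury and fell after larvae in edgeR (4 at unadjusted p under 0.05, DESeq2 0). There 5 fell after injury and rose after larvae, namely chorismate mutase, Tatro_003634-T1 (-0.37 and 0.73), and Tatro_003726-T1, Tatro_000349-T1, Tatro_005912-T1 and Tatro_006513-T1, which have no product text. Against CT0 3 of the 5 passed again, but not Tatro_003726-T1 (-0.14 after injury) nor Tatro_006513-T1 (0.64 after larvae). At 8 h 1 gene, the MFS transporter Tatro_007357-T1, rose after injury and fell after larvae (0.46 and -0.52). Against CT0 its change after injury was -0.02 and not past the threshold, so its opposite direction rests on the control. None fell after injury and rose after larvae in edgeR (0, with 1 at unadjusted p under 0.05, DESeq2 0).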

How the results depend on the processing

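Alternatives chosen after seeing the data are listed above. Counts of changed genes stayed within 1.5 times under the alternatives tried, except as follows, and the cause was not tested unless named. In Of_4h DESeq2 gave 52. A fit of only the 6 libraries compared gave 1274 in Dm_90min, 1444 in Dm_8h, 672 in Of_4h, 1 in Of_8h, 77 and 11 for larvae against injury at 90 min and 8 h, and 1883 and 1126 for larvae against O. folsomi at 90 min and 8 h. With the other control counts were 1025 in Dm_4h, 368 in Of_30min, 3 in Of_90min, 1193 in Of_4h and 795 in Of_8h. With the mean of both controls they were 545, 13, 408 and 12 in the 4 O. folsomi groups. Without the 4 shallow libraries Of_90min had 770 and Of_4h 45, and with library totals alone Of_4h had 32. Whether rises or falls were the majority often depended on the setting. The next counts leave aside the fits with each library left out in turn, but include the fit without the 4 shallowest. Of 11 such alternatives the majority turned in 5, 7, 5 and 7 after injury, 7, 9, 2 and 6 after larvae, and 2, 1, 2 and 0 after O. folsomi from 30 min to 8 h. Of 9 alternatives it turned in 6, 1, 1 and 1 for larvae against injury, 7, 1, 0 and 6 for larvae against O. folsomi, and 0 for CT8 against CT0. In MI_30min it turned, for example, without the filter (2095 up and 2060 down), and in Dm_90min with DESeq2 (1552 up and 1434 down).

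Thinning removes counts, and it gave 1235 in MI_4h, 1083 in MI_8h, 1080 in Dm_4h, 1480 in Dm_8h, 439 in Of_30min, 240 in Of_90min, 3 in Of_4h, 1834, 713, 283 and 81 for larvae against injury from 30 min to 8 h, 1432 and 1347 for larvae against O. folsomi at 4 and 8 h, and 390 for CT8 against CT0.

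With 1 library left out, which also leaves fewer samples, counts ranged as follows. After injury they were 3515 to 3947, 2911 to 3472, 1406 (without MI_4h replicate 1) to 1922 and 1360 (without CT8 replicate 1) to 1848 from 30 min to 8 h. After larvae they were 2985 to 3446, 2449 to 3085, 1327 to 1513 and 1668 to 2475. After O. folsomi they were 438 to 695, 203 to 513, 0 to 21 and 0 to 0. Single counts after O. folsomi are in the results above. For larvae against injury they were 2328 to 2659, 360 to 1488, 201 to 528 and 39 to 449. At 90 min they were 360 and 643 without MI_90min replicate 1 and Dm_90min replicate 3. At 4 h they were 201, 241 and 311 without MI_4h replicate 1 and Dm_4h replicates 1 and 3, and at 8 h 39, 54, 63 and 449 without MI_8h replicates 2 and 3 and Dm_8h replicates 1 and 3. For larvae against O. folsomi they were 3152 to 3648, 2638 to 3164, 1723 to 2063 and 1359 to 2206, and for CT8 against CT0 386 to 736, with 386, 414 and 426 without CT0 replicate 3 and CT8 replicates 1 and 3.

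Named genes that reversed against the other control were Tatro_003677-T1 (-0.319 in MI_90min, -0.166 in Dm_90min, 0.295 in Dm_4h, -0.271 in Of_30min, -0.094 in Of_90min, and -0.001 in MI_90min with the mean of both controls), Tatro_005384-T1 in MI_8h (-0.055) and Tatro_008667-T1 (-0.061 in Dm_90min, -0.056 in Of_30min). Others were Tatro_010407-T1 (-0.474 in Of_30min, -0.183 in Of_90min), Tatro_003383-T1 (-0.428 and -0.190) and Tatro_005163-T1 (-0.405 in Of_30min). In Of_90min they were also Tatro_006408-T1 (-0.155), Tatro_000263-T1 (-0.139), Tatro_008157-T1 (-0.043), Tatro_002100-T1 (-0.026), Tatro_002602-T1 (-0.058) and Tatro_000708-T1 (-0.028), and in Of_4h Tatro_005313-T1 (0.570). Among pairs of a named gene and a comparison, calls were lost for 40 with the other control, 32 with the mean of both, 39 with only 6 libraries, 30 when thinned, 15 without the shallow libraries, 12 with library totals, 6 without the filter, 2 with RLE factors, 2 with every model and 0 with DESeq2.

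Of the 58 list calls the estimated correlation left 0 and all tested genes as background 55 (lost were transcription factors and cell cycle genes in Dm_90min and MFS transporters for larvae against injury at 8 h, at adjusted p of 0.074, 0.082 and 0.063), while that background gave 91 calls in all and fry, which tests another question, 149. With the replicate block all 58 list calls were kept, 4 named pairs lost their call, and the counts were 877, 470, 23 and 0 in the O. folsomi groups. The mean correlation of libraries with the same number was -0.006, 0.000 and 0.010 for the 3 numbers, and 15 of 42 libraries lay nearest to their own number, so the numbers do not pair the libraries.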

Other observations

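The comparison of larvae with the later injury groups, the DNA repair median, the tests of the CT0 group and the enrichment of product texts were chosen only after the result was seen. Genes with a nucleophile aminohydrolase text, the fold of 20S proteasome subunits, were more often higher after larvae than after injury at 90 min than other genes with a text. They were higher in 7 of 8 cases, against 317 of all 2865 genes with a text (two-sided Fisher's exact test over genes, which are not independent, adjusted p = 0.00015 over 110 tests in that comparison). After injury at 90 min 5 of the 8 fell (median -0.31). At 30 min genes with a text of helicase superfamily 1/2 were more often lower after larvae than after injury, in 9 of 12 cases against 656 of 2865 (same test, adjusted p = 0.01). So were genes with an AAA+ ATPase text (23 of 46, same test, adjusted p = 0.0057) and a fungal transcription factor text (20 of 43, same test, adjusted p = 0.025). All 12 helicase genes rose at 30 min after injury, against 1355 of 2865. The same injury libraries enter both comparisons and the selection of the genes, so the lower level after larvae is not independent of that selection. All of these texts belong to genes that the study called at 30 min after injury.

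Larvae and injury were also compared with no control library in common, injury against one control and larvae against the other. The log2 changes correlated across 9193 genes, which are not independent replicates, with Pearson's r of 0.60 at 30 min, 0.71 at 90 min, 0.51 at 4 h and 0.66 at 8 h. Between injury and O. folsomi r was 0.20, -0.00, -0.24 and 0.01. Replicate 3 of Dm_90min lay 0.715 (root mean square log2) from its group mates, against at most 0.616 in other groups.

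Dm_30min differed from MI_30min in 2882 genes and from MI_90min in 817, and all 3 of its libraries lay nearer to MI_90min. Depth is argued against as the whole cause, since 1834 genes differed when all libraries were thinned to the shallowest. A candidate explanation is that larva-grazed mycelium is further along the course that injured mycelium follows. The DNA replication and repair list had a median of 0.10 against MI_90min (95% bootstrap interval over genes 0.03 to 0.26). This lay at the edge of the range set. It cannot decide, since medians against CT0 were 0.09 in Dm_30min and -0.08 in MI_90min. Genes never raised after larvae would lie as near. The later times leave the explanation open. By root mean square log2 difference Dm_90min and Dm_4h lay nearest to injury of the same time (0.435 and 0.361). The next later injury group followed (0.464 and 0.402). Dm_90min differed in 958 genes from MI_4h and 1078 from MI_90min, and Dm_8h has no later injury group. At the times sampled 149 genes (5.17%) lay outside all 4 injury groups in the same direction, 89 higher and 60 lower after larvae. This share lay between the bounds set beforehand for and against the explanation, so it does not decide. Of the 149, 61 held in a joint test of the 4 comparisons and stand against the explanation at those times. Stages between those times, which were not measured, leave it open for them. For the rest of the 149 chance stays open as well.

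Of the 503 genes called at 90 min after O. folsomi against CT0, 0.199% (1 gene) were called in the same direction against CT8, which may come from the CT0 group standing apart from the later untreated libraries. The shallow CT0 replicate 2 is argued against as the cause, since 481 genes were called without it, while 203 were called without CT0 replicate 3, and 311, 243 and 326 without Of_90min replicates 1, 2 and 3. At 30 min 135 of 910 genes (14.8%, 46 up and 89 down) were called in the same direction against CT8, a comparison with no CT0 library in which the threshold allows 18.4 false calls, so the CT0 group is argued against as their cause, while the later time of CT8 stays open. That number was 71 without CT8 replicate 3, 56, 48 and 78 without Of_30min replicates 1, 2 and 3, 77 without the shallow libraries, 70 when thinned, 228 (14 up and 214 down) with library totals alone and 314 in a fit of only these 3 groups. For the other 775 genes the CT0 group and a response to the grazer cannot be told apart, since a missed call against CT8 excludes neither, and the 910 became 546 without CT0 replicate 3 and 560, 438 and 445 without Of_30min replicates 1, 2 and 3.

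Genes with neighbouring ID numbers changed together. In Dm_30min 134 neighbouring pairs changed at least 2-fold in the same direction, against a median of 36 and at most 58 in 1000 shuffles, so a chance order of the IDs is argued against. The longest run was of 6 genes, Tatro_000353-T1 to Tatro_000358-T1, with a catechol dioxygenase and an amidohydrolase among the products (log2 -4.91 to -1.50). The median residual correlation of the pairs was 0.37 (95% bootstrap interval over pairs 0.25 to 0.48), under the bound of 0.5 set for reads of overlapping neighbours counted for both as the cause of the whole pattern, but above the 0.06 of all neighbouring pairs. Such reads stay open for part of the pairs, 50 of which were over 0.5 (558 of all 7509), shared regulation is a candidate explanation that was not tested, and that the ID order follows the genome is assumed.

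With 3 libraries a group, the 10 splits of 6 libraries are too few for a share under 0.05. In fits of the 6 libraries alone the real split called 4145, 2829, 3119 and 2962 genes after injury, 2630, 1274, 2652 and 1444 after larvae, and 953, 500 and 672 after O. folsomi from 30 min to 4 h. It called 2624, 77, 622 and 11 for larvae against injury, 3584, 1883, 2932 and 1126 for larvae against O. folsomi, and 911 between the controls. In these, the highest count of any other split was 2 (larvae against injury at 90 min) and otherwise 0, so 1 of the 10 splits, the real one, gave as many. In Of_8h the real split called 1 gene and the highest other 17, and 8 of the 10 splits gave at least as many.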
